A study of Danio rerio with 2 samples.

How the data were processed

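Chromatin accessibility was profiled by ATAC-seq, in which a transposase cuts open DNA and adds sequencing adapters, in cells of the zebrafish line Tg(CD41:GFP,gata1:dsRed). Flow cytometry kept cells that were positive for the CD41 reporter and negative for the gata1 reporter, which the labels call hematopoietic stem cells. The labels give 1 group of 2 replicates, and the sample titles carry the tag 3m, whose meaning is not spelled out there. Nothing in the labels says that the replicates came from separate animals or separate sorts, so the spread between them may be technical. The labels' protocol describes transposition of fresh cells with a Vazyme kit, PCR amplification without molecular identifiers and Illumina sequencing.

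The authors deposited 1 peak list per replicate, so peaks were called per sample. Per the submitters' processing notes, Bowtie2 2.5.0, SAMtools 1.9, Picard, MACS2, HTSeq 0.8.0 and DESeq2 were named for this series, without their roles or order, and the build was GRCz10. The peak names carry abbreviations for sorting, removal of duplicates and a chromosome filter, per the file contents. The settings of the peak caller, any shift of reads for the transposase offset and the significance threshold were not given in the sources used here. A missing or different shift would move summits and peak edges by a few bases.

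In the deposited lists, the fold enrichment is the ratio of the summit pileup to the local background as the authors' peak caller wrote it. The deposited score of each peak equals 10 times its −log10 q value, cut to a whole number, in 100% of the peaks of both lists. The deposited −log10 p and −log10 q values are those of the authors' peak caller. Positions and summit offsets were used as deposited by the authors and are printed 1-based in GRCz10.

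The summit pileup, the number of extended reads that cover the summit, was recovered from each peak's fold and −log10 p. The fold was taken as the pileup plus 1 over the background plus 1, and the p value as the upper Poisson tail above the pileup. A whole-number pileup that matched the deposited −log10 p within 0.0002 was found for 33700 of 33700 nuclear peaks in replicate 1 and 15814 of 15814 in replicate 2. In replicate 2, 29 peaks had a second matching pileup. All nuclear backgrounds above the lowest value were multiples of 0.02 within 0.0004, the step that a read extended to 200 bp makes in a 10 kb window. The lowest background, taken as the genome-wide one, was 1.32 extended reads per position in replicate 1 and 0.578 in replicate 2. Their ratio, 2.28, served as the relative depth, since read totals were not used here. Pileups of the mitochondrial peaks were approximate, with errors of up to 0.00691 in −log10 p.

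Nuclear peaks on the 25 chromosomes entered all comparisons, and mitochondrial peaks were kept apart. Peaks were shared when they overlapped by at least 1 bp. Overlapping peaks of both lists were merged into regions. The observed overlap was set against 1000 placements of the replicate 2 peaks shuffled within their chromosome, in a one-sided permutation test. Each chromosome was taken to end at the largest peak end in either list, a span of 1339.57 Mb in all. Fold enrichments and pileups were correlated across one-to-one pairs of shared peaks, and peaks are not independent replicates. Shared regions per Mb were compared with 1000 shuffled placements over the whole genome, in two-sided permutation tests with Benjamini-Hochberg adjustment over 25 chromosomes, at an adjusted p of 0.05. Chromosome 4 was also split at 27 Mb. Shares carry 95% Wilson intervals, which cover counting error only.

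A test for single peaks was chosen after the data were seen. It set the 2 pileups of each of the 13094 pairs against the ratio of the summed pileups, 2.12, by a two-sided exact binomial test with Benjamini-Hochberg adjustment. It compares these 2 libraries and treats extended reads as independent, although summits were picked for their height. Peaks past the threshold within 100 kb of each other were joined into loci.

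The peaks named by position followed a rule fixed before the data were examined: the 10 shared peaks with the highest lower fold of the pair, and the 5 peaks of each replicate with the highest fold that the other list lacks. Other positions were chosen after their values were seen. The planned shares of peaks at promoters, exons and introns, promoter and distal accessibility of 20 gene lists and enrichment of 32 motifs were not run. They need a GRCz10 genome and annotation, and the gene tables at hand either belong to GRCz12tu or carry no coordinates. For the same reason shuffling outside assembly gaps was not run, no gene is named and no sequence is given.

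The alternatives were stricter −log10 q minimums of 5 and 10, lists of equal length, reciprocal overlap of 50% of both peaks, summits within 150 bp, and each replicate alone. Added after the data were seen were a local shift of replicate 2 peaks by 10 to 50 kb, shuffling of whole 1 Mb bins, and 5 other settings of the binomial test.

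Pileup recovery, overlap, shuffling within chromosomes and the binomial test were tested on simulated data; the tests along chromosomes and the expected number of peaks at lower depth were not. The pileup was recovered in 100% of 2000 simulated peaks, and 0% of 1346 simulated fractional pileups matched. With 15814 simulated peaks and no planted overlap, the excess over shuffling was 0.093%. In 13094 simulated pairs for the binomial test, 73% of pairs raised 4-fold in replicate 1 and 71% of those raised in replicate 2 were called, and 11 unchanged pairs were called. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.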

Results

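Open chromatin was mapped in CD41+ gata1− cells sorted from zebrafish that carry both reporters, in 2 ATAC-seq replicates of 1 group. CD41 is an integrin subunit found on thrombocytes and on early blood stem and progenitor cells, and Gata1 is the leading transcription factor of red cell development. The series concerns chromatin folding during blood stem cell development, and its design text gives accessibility, together with other data, as a basis for studying transcription factors. The labels name no second group, so the comparison made here is that between the replicates, followed by the distribution of shared sites over the genome.

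The replicate 1 list held 33708 peaks and the replicate 2 list 15821. They covered 11.3 and 6.03 Mb, or 0.842% and 0.45% of the 1339.57 Mb spanned by nuclear peaks. The median nuclear peak was 282 bp wide in replicate 1 and 322 bp in replicate 2. The fold enrichment given by the authors' peak caller had a median of 5.69 in replicate 1 and 6.50 in replicate 2. The median summit was covered by 15 extended reads in replicate 1 and 13 in replicate 2. Genome-wide background coverage was 1.32 and 0.578 extended reads per position, which puts the depth of replicate 1 at 2.28 times that of replicate 2.

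The first question was whether the replicates mark the same sites. They shared 13698 accessible regions of 35191 in all. Of the replicate 2 peaks, 13868 overlapped a replicate 1 peak, which is 87.7% (95% Wilson interval 87.2 to 88.2). In the other direction, 14153 replicate 1 peaks had a partner in replicate 2, or 42.0% (95% Wilson interval 41.5 to 42.5). Shuffled placements gave 1.79% of replicate 2 peaks on average and 2.13% at most, and the permutation p of 0.001 is the smallest that 1000 shuffles can give. The intervals on these and later shares cover counting error only.

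Ranked by the lower fold of each pair, the 10 strongest shared sites had folds of at least 20.8 in both replicates. On chromosome 17, the peak at 53292511 to 53292959 had a fold enrichment of 32.5 in replicate 1 and 25.3 in replicate 2, the highest lower value of all shared peaks. Chromosome 10 held the next, at 27010814 to 27011198, with folds of 27.1 and 24.1. A second site on chromosome 17, at 1610349 to 1611143, reached 28.8 and 24.0, and both summits fell on position 1610540. The peak on chromosome 20 at 4437601 to 4438039 had a fold of 38.3 in replicate 1 and 23.7 in replicate 2. On chromosome 3, the site at 1338103 to 1338598 had folds of 28.1 and 22.3. The site at 11943339 to 11943789 on chromosome 21 had folds of 25.5 and 22.2. Chromosome 2 carried a pair of these sites, at 55564880 to 55565592 with 23.7 and 22.0 and at 48219715 to 48220152 with 27.4 and 20.8. The remaining members of the 10 strongest lay on chromosome 8 at 5221973 to 5222668, with 23.9 and 21.9, and on chromosome 13 at 46423267 to 46423756, with 25.9 and 20.8. The peaks at 53292511 on chromosome 17 and at 4437601 on chromosome 20 also differed in height between the libraries beyond the depth ratio, as given further on.

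Among 13094 one-to-one pairs of shared peaks, the summits lay a median of 28 bp apart, and 88.6% were within 150 bp. Across these peaks, which are not independent replicates, the Spearman correlation of fold enrichment was 0.72 and the Pearson correlation of log2 fold was 0.75. Summit pileups had a Spearman correlation of 0.794. When both lists were held to their 1000 strongest peaks by the authors' q value, 70.1% of those of replicate 2 were shared (95% Wilson interval 67.2 to 72.9). With 15814 peaks in each list the share was 70.9%.

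The chance of finding a site again rose with its strength. Replicate 1 peaks with a fold under 4 were found in replicate 2 in 9.78% of cases (95% Wilson interval 8.96 to 10.7, n = 4569), and those with a fold of 16 or more in 99.4% (98.9 to 99.7, n = 1395). For replicate 2 peaks the share rose from 52.5% under a fold of 4 (48.3 to 56.6, n = 551) to 100% at a fold of 16 or more (lower bound 98.5, n = 246).

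**Figure D1:**
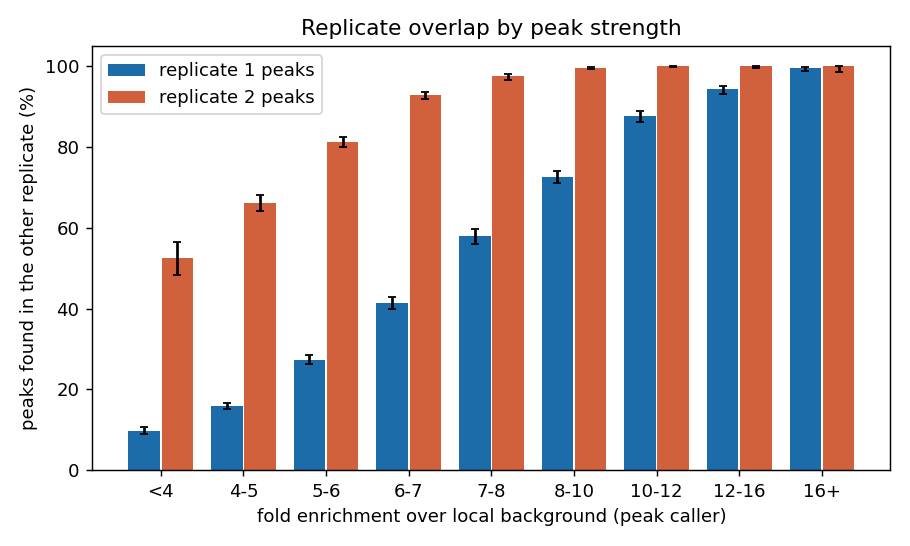
Percent of the peaks of each replicate that overlap a peak of the other (vertical axis), by the peak caller's fold enrichment (horizontal axis), with replicate 1 in blue and replicate 2 in orange and 95% Wilson intervals as error bars. The share climbs from 9.78% to 99.4% in replicate 1 and from 52.5% to 100% in replicate 2.

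Sites seen in a single replicate numbered 19547 in replicate 1 and 1946 in replicate 2. With lists of equal length the numbers were 4562 and 4601, and with a −log10 q of at least 10 they were 7727 and 212. In the full lists they were weak and narrow next to shared sites. Their median fold was 4.80 against 8.42 for shared peaks in replicate 1, and 4.89 against 6.90 in replicate 2. Their median width was 241 bp against 382 bp in replicate 1, and 211 bp against 347 bp in replicate 2. The shared peaks of the same fold were also wider, with medians of 401 against 292 bp in replicate 1 for folds of 8 to 10. No test between groups applies to these 2 lists.

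The strongest peak of replicate 1 without a partner lay on chromosome 24 at 18702893 to 18703272, with a fold of 18.8 and a summit pileup of 54. The other 4 lay on chromosome 14 at 49775892 to 49776181, chromosome 5 at 64170669 to 64170971, chromosome 11 at 38119493 to 38119786 and chromosome 23 at 44007276 to 44007569, with folds of 17.1, 17.0, 17.0 and 16.4. In replicate 2 the strongest unmatched peak lay on chromosome 17 at 25612362 to 25612575, with a fold of 8.76, and lay 0.225 kb from a replicate 1 peak. The next, on chromosome 19 at 32931092 to 32931568, had a fold of 8.50 and lay 24.0 kb from the nearest replicate 1 peak. The last 3 were on chromosome 7 at 14144757 to 14144970, chromosome 21 at 4530821 to 4531116 and chromosome 17 at 16317033 to 16317275, with folds of 8.27, 8.25 and 8.22. Each of these lay within 0.681 kb of a replicate 1 peak.

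For most shared sites no difference in height beyond the depth ratio was detected, and a small set differed. Of 13094 shared peaks, 50 differed in summit pileup past an adjusted p of 0.05 in an exact binomial test chosen after the data were seen, 45 higher in replicate 1 and 5 higher in replicate 2. The pileup ratio of replicate 1 to replicate 2 at the 45 peaks had a median of 6.84 and ran from 3.49 to 11.1. The median was 2 over all pairs, many of them weak. It was 2.31 over the 3564 pairs with at least 60 extended reads in sum, which all 45 peaks had. In simulated data the test called 73% of pairs raised 4-fold in replicate 1 and 71% of those raised in replicate 2. Among changed pairs with at least 60 extended reads in sum it called 100%. At weak sites the lack of a call therefore says less. These 45 peaks fell into 33 loci, of which 7 held several peaks. At the 5 peaks higher in replicate 2 the ratio ran from 0.5 to 0.971.

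The peak on chromosome 14 at 19788790 to 19789521 had the smallest adjusted p, with 783 extended reads at its summit in replicate 1 and 97 in replicate 2 (exact binomial test, adjusted p = 3.78e-44). The chromosome 20 peak at 4437601 had 706 and 91 (adjusted p = 3.11e-38, exact binomial test). On chromosome 10, 6 peaks between 16831213 and 16881888 were all higher in replicate 1, with a median ratio of 7.73 and 467 against 42 extended reads at the highest. The peak caller's fold differed less at these 6 peaks, with 14.0 against 9.23 at the highest and 4.65 against 4.87 at 16840522. Over all 45 peaks the ratio of the folds had a median of 1.41, against 1.22 over all pairs, and it was below 1 at 3 peaks. Between 52740091 and 52744143 on chromosome 7, 3 peaks had a median ratio of 8.81. The chromosome 17 peak at 53292511, the first of the strongest shared sites, had 565 and 162. The peak with the smallest adjusted p among those higher in replicate 2 lay on chromosome 16 at 29623727 to 29624555, with 68 extended reads in replicate 1 and 70 in replicate 2, where depth alone would give more in replicate 1. The test compares 2 libraries and says nothing about animals or conditions. With both peaks of a pair held to a −log10 q of at least 10, 30 peaks passed. The split was 33 higher in replicate 1 and 9 in replicate 2 with the depth ratio of the genome background. With the median ratio of all pairs it was 65 and 4. Among pairs with at least 60 extended reads in sum, tested against their own median ratio of 2.31, it was 44 and 12.

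**Figure D2:**
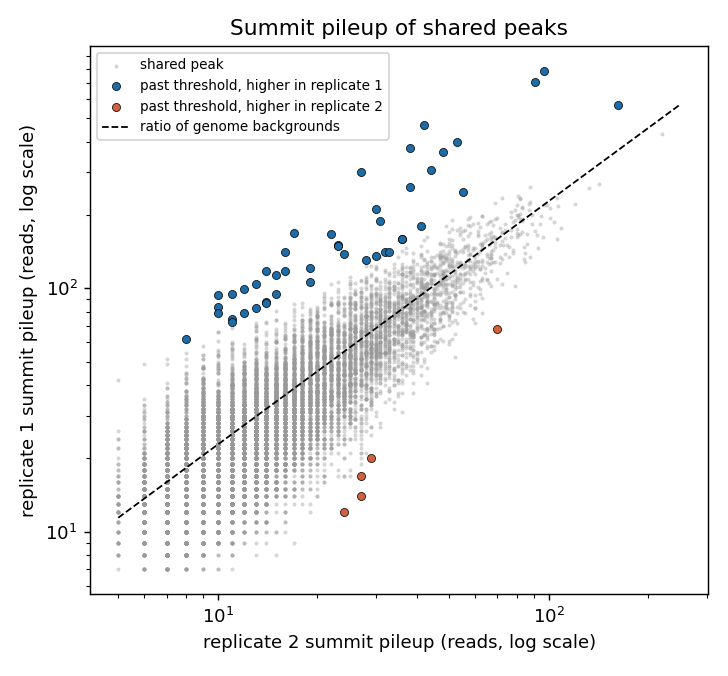
Summit pileup of each shared peak in replicate 2 (horizontal, extended reads, log scale) and replicate 1 (vertical, extended reads, log scale), with 13094 pairs in grey and the genome background ratio of 2.28 as a dashed line. The 45 peaks higher in replicate 1 (blue) lie above the band and the 5 higher in replicate 2 (orange) below it.

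**Figure D3:**
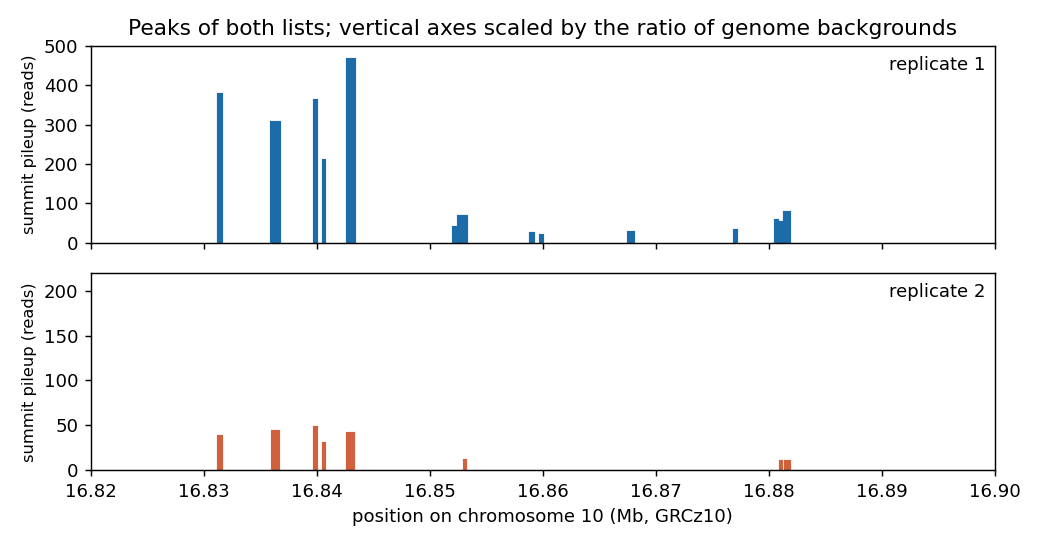
Peaks of replicate 1 (upper panel) and replicate 2 (lower panel) on chromosome 10, drawn at their GRCz10 positions with the summit pileup in extended reads as height; the vertical axes differ by the background ratio of 2.28. The 6 peaks past the threshold between 16831213 and 16881888 stand higher in replicate 1, up to 467 against 42 extended reads.

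The second question was how shared sites are spread over the chromosomes. The genome held 10.2 shared regions per Mb. Chromosome 4 stood apart, with 5.63 per Mb, or 0.536 times the density of all others (permutation p = 0.001, the smallest that 1000 shuffles can give, adjusted p = 0.00833). The long arm of this chromosome is known as gene-poor and heterochromatic in zebrafish. Before 27 Mb it carried 322 shared regions, or 11.9 per Mb, and from 27 Mb on 109, or 2.2 per Mb. The second part had 0.209 times the density of the rest of the genome (permutation p = 0.001, the smallest possible). The shuffles did not leave out assembly gaps or stretches where reads cannot be placed. Closed chromatin can therefore not be told apart from missing or unmapped sequence. Local background at peaks after 27 Mb was also lower, a median of 1.46 extended reads against 1.76 before it in replicate 1. In replicate 2 it was 0.94 against 1.06.

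The sparse stretch did not reach the chromosome end. In parts chosen after the counts were seen, 35 shared regions lay between 30 and 70 Mb, or 0.875 per Mb, and 18 of the 40 bins of 1 Mb there had none. From 70 Mb to the last peak there were 57 regions, or 8.64 per Mb. Each list alone gave the same order, with 4.38 replicate 1 peaks per Mb between 30 and 70 Mb and 22.9 beyond, and 1.30 and 10.9 for replicate 2. Peaks after 27 Mb were also found again less often in the counts, with 29.4% of 388 replicate 1 peaks shared against 45.7% of 737 before 27 Mb. They were weaker too, with a median fold of 5.12 against 5.98 in replicate 1, and weaker peaks were shared less often genome-wide. The difference in shares was not tested.

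**Figure D4:**
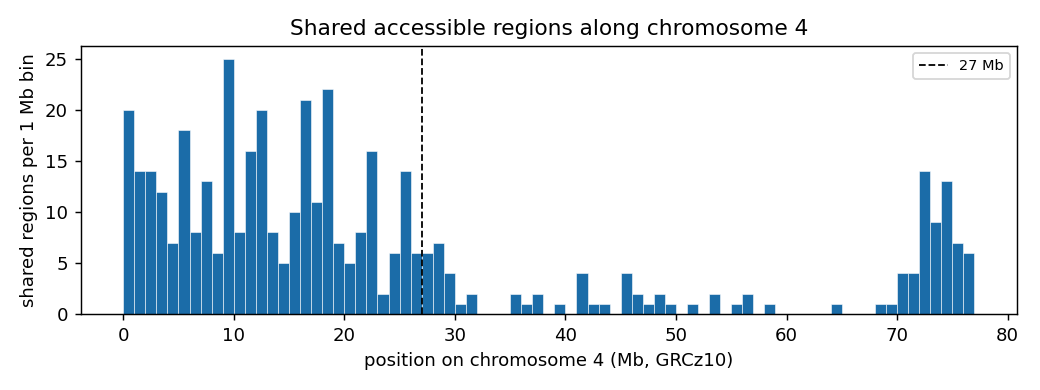
Shared accessible regions per 1 Mb bin along chromosome 4 (vertical axis, number of regions; horizontal axis, GRCz10 position in Mb), with the split at 27 Mb dashed. Bins between 30 and 70 Mb hold 35 regions in all, and those from 70 Mb on hold 57.

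Of the 25 chromosomes, 6 passed the adjusted threshold, and 10 passed when replicate 2 was left out and all replicate 1 peaks were counted. Chromosome 12 was low besides chromosome 4, with 9.02 shared regions per Mb (adjusted p = 0.0417). Chromosomes 3, 5, 6 and 19 were high, at 11.6, 11.4, 11.5 and 11.6 per Mb, with ratios to the rest of 1.15, 1.12, 1.13 and 1.15. Chromosome 4 before 27 Mb had 1.17 times the density of the rest (permutation p = 0.009). When whole 1 Mb bins were shuffled, which keeps neighbouring sites together, 1 chromosome passed, chromosome 4 (adjusted p = 0.025), and its part before 27 Mb did not (permutation p = 0.099).

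**Figure D5:**
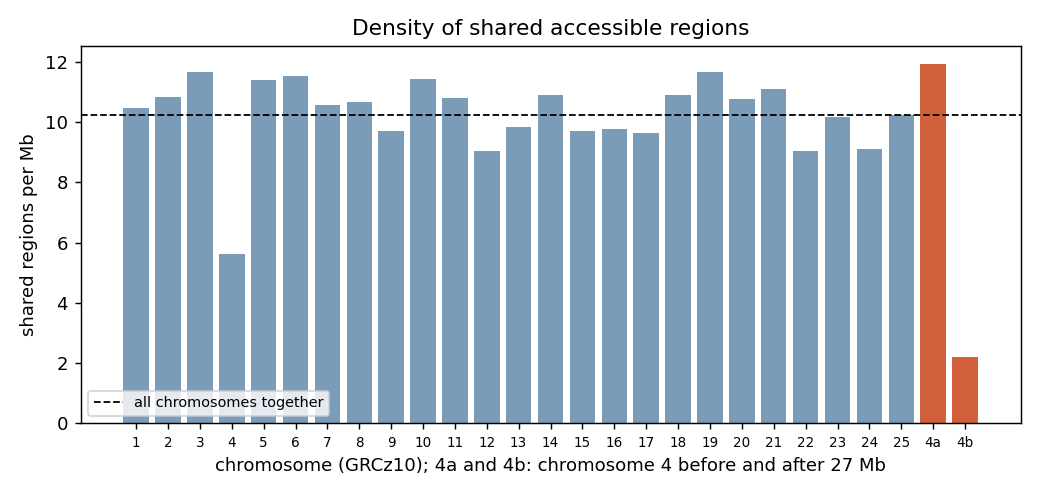
Shared accessible regions per Mb (vertical axis) for each of the 25 chromosomes in pale blue and for chromosome 4 before (4a) and after (4b) 27 Mb in orange, with 10.2 per Mb over all chromosomes dashed. Chromosome 4 lies at 5.63, its first part at 11.9 and its second at 2.2.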

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

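The comparison of mitochondrial and genome-wide backgrounds was chosen after the values were seen. Mitochondrial peaks entered no comparison and drew attention as signal outside the nuclear lists, with 8 peaks in replicate 1 and 7 in replicate 2. In all, 7 matched between the lists. Their folds were low, from 1.39 to 1.98 in replicate 1 and from 1.44 to 1.92 in replicate 2, over backgrounds about 6999 and 8024 times the genome-wide one. The mitochondrial background of replicate 1 was a median of 1.91 times that of replicate 2 (1.81 to 1.97 over the 7 peaks), against 2.28 for the genome-wide background. Whether mitochondrial reads count in the genome-wide background was not checked. No explanation was tested for these values.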

How the results depend on the processing

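The tests by shuffled 1 Mb bins and local shifts and all settings of the test of single peaks were chosen after the data were seen. No paired analysis was possible because the labels give 1 group. Of 73 values under alternatives, 46 stayed as reported, which means a count within 1.5 times, a share or correlation within its 95% interval, or a tested value with the same direction and side of the threshold; 25 moved beyond that, 2 lost their side of the threshold and none reversed, and where they changed the cause was not tested unless fewer peaks entered. Fewer peaks entered with a −log10 q of at least 10: 13293 and 5664 peaks in the lists, 5433 shared regions, 7727 and 212 peaks of 1 replicate only, a Spearman correlation of 0.711, a density ratio of 1.11 for chromosome 4 before 27 Mb (permutation p = 0.26), and 30 peaks differing in height, 27 higher in replicate 1 and 3 in replicate 2. With a minimum of 5, 12433 and 944 peaks were in 1 list only, 47.0% of replicate 1 peaks were shared and the correlation was 0.692. Equal list lengths gave 4562 and 4601 unshared peaks, 71.2% of replicate 1 peaks shared and a correlation of 0.691. Reciprocal overlap gave 4154 unshared replicate 2 peaks and 34.6% of replicate 1 peaks shared, and summits within 150 bp gave 36.1% and a correlation of 0.731. With whole bins shuffled, 1 chromosome passed. Chromosome 4 before 27 Mb had a permutation p of 0.099, and its ratio of 1.17 was the same by construction. Each replicate alone gave 6 to 10 chromosomes past the threshold, 10 with replicate 1. Peaks higher in replicate 2 numbered 9 with the genome background ratio and 12 among pairs with at least 60 extended reads in sum and their median ratio. The low density of chromosome 4 kept its side under every alternative run for it. Its ratios were 0.481 to 0.569 in whole and 0.159 to 0.303 after 27 Mb. The excess of shared peaks over chance kept its side with stricter q minimums, equal list lengths and local shifts, with shares of 70.9% to 96.3%. For reciprocal overlap and summits within 150 bp, only the 1 bp overlap was set against chance, so their own shares were not tested. Both still count among the 46 values that stayed as reported. So do the alternatives for the strongest shared peaks, which were picked from peaks already shared. Weak sites were found again least often, with 6.83% of replicate 1 peaks of at most 10 extended reads present in replicate 2. How much of this depth sets was left open, as depth gave 34.0% on summit height alone and 1.15% with a minimum width. Gene, motif and assembly-gap alternatives were not run.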

Other observations

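The tests in this part were chosen after the results were seen, except the share of replicate 2 peaks found in replicate 1, its chance level and its value at equal list length, which were planned. Shared sites were denser at chromosome ends. The first and last whole 1 Mb bins of the 25 chromosomes, with the partial bins beyond left out, held 14.2 shared regions per Mb against 9.99 in the bins between, a ratio of 1.43 (one-sided permutation p = 0.0001, the smallest that 10000 permutations can give), and 20 of 25 chromosomes had the higher mean at their ends. Background coverage at the peaks was also higher there, with medians of 1.9 against 1.7 extended reads in replicate 1 and 1.1 against 1.02 in replicate 2.

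The densest 100 kb windows each held 10 shared regions, at 38500001 to 38600000 on chromosome 14, 43300001 to 43400000 on chromosome 2 and 7100001 to 7200000 on chromosome 3. In 1000 shuffles the densest window held a median of 7 and at most 10 regions. The highest summit in replicate 2 belonged to a broad site on chromosome 5 at 825923 to 827943, 2016 bp wide in replicate 1, with 430 and 220 extended reads over local backgrounds of 45.9 and 22.0.

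The shorter list of replicate 2 was set against 3 explanations. Mostly different sites being open there runs against the 87.69% of its peaks found in replicate 1, where chance gave 1.79%, although the share was 70.9% when the replicate 1 list was held to the same length. Lower depth acting on summit height alone predicted 1.673 times the observed number of replicate 1 peaks found again. This overshoot cannot decide the matter by itself. Replicate 1 summits were picked for their height, which raises the prediction for weak peaks, and this step was not simulated. Lower depth together with a minimum width of 200 bp gave 0.7647 times the observed number under an assumed triangular peak shape. A mixture of both limits may account for the total found again, which stays open because the true peak shapes were not used here. Of 4284 replicate 1 peaks with at least 40 extended reads, 149 were missing from replicate 2. Summit height alone gave 4.58 missing there and the width limit 102, both fewer than observed. No mixture of the 2 limits as modelled reaches that number. The difference was not tested, and these strong peaks were also picked by their replicate 1 height. The assumed peak shape enters here too, so lower depth is not excluded for them. Among replicate 1 peaks of at least 40 extended reads, 74 of 315 under 300 bp wide were missing from replicate 2, against 6 of 1086 of at least 600 bp.

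The loci higher in replicate 1 were set against 3 technical explanations. Library depth alone runs against the 44 peaks called higher in replicate 1 (exact binomial test, Benjamini-Hochberg adjusted) when all 3564 pairs with at least 60 extended reads in sum were tested against their own median ratio of 2.31. The p values of that test cover counting error only and treat extended reads as independent. Extra DNA spread evenly over 10 kb would add as much to the background as to the summit. The background excess was a median of 0.06463 times the summit excess and at most 0.251 times. Peaks enter the lists by standing above their local background, which by itself tends to hold this ratio low. The values show that the excess at these peaks lay mostly at the summit, and they cannot exclude such DNA. Extra copies of a wide region cannot be told apart from local differences. The 82 shared peaks within 100 kb, 19 of them called themselves, had a median ratio of 2.25 and an upper quartile of 5.76. Without the called ones, the 63 others had a median ratio of 2.04, against 2 over all pairs, though being uncalled selects for low ratios. Reads in the 10 kb around the called peaks, which include the peaks, had a median ratio of 8.27. No biological explanation was tested, and a different mixture of sorted cells or animals could still lie behind the loci.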
